A study of Homo sapiens with 6 samples.

How the data were processed

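Chromatin of exponentially growing HCT116 cells was crosslinked with formaldehyde, sheared by sonication and immunoprecipitated with a custom rabbit antibody to acetylated NEIL1, per the labels' protocols. Groups and replicate numbers were taken from the sample labels. The authors deposited a peak table for each of the 3 ChIP libraries. The 3 input libraries entered through these tables only, as the control of the ChIP library with the same number; their own values were not analysed here.

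Peaks were called with MACS 2.1.1.20160309, per the file headers, for each replicate on its own and without pooling, in single-end mode, with a q-value cutoff of 0.05 and the larger library of a pair scaled to the smaller. At most 2 tags per position were kept, per the file headers. Trim Galore, FastQC, cutadapt, Bowtie2, SAMtools, bedtools and MACS2 are listed in the submitters' processing notes; the versions of the others and the role of each are not given in the sources used here. The notes list GRCh37 and GRCh38 under several names, and the tables themselves are in hg38, per the file headers; all coordinates are 1-based in hg38.

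The deposited signal is the pileup height at the peak summit, in tags extended to a fragment length of 268, 294 and 249 bp in replicates 1, 2 and 3, per the file headers. The deposited −log10 values are those of the caller's Poisson p and of its q against the local background. The fold enrichment, a ratio of the pileup to the local background with 1 added to each, is the authors' own value per peak. It was used to describe, rank and filter peaks within a list, to correlate peak strength between replicates and to recover the local background. The fold of a merged region or of a gene in a replicate is that of its strongest peak there. The local background at each summit was recovered from the pileup and the fold, and had a floor of 3.14 ± 0.0353 tags (SD, n = 3).

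Depth was 31921768, 28814429 and 35222701 tags in the ChIP libraries and 32877739, 37772127 and 33606858 in the inputs of replicates 1, 2 and 3 after the duplicate filter. The peak lists give no counts outside peaks, so a gene without a peak is a gene at which none passed the caller's cutoff at this depth. A count of 0 genes was given the upper limit that 3 of the total would set.

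Peaks on chromosomes 1 to 22 and X were kept. Merged regions were formed with an overlap of at least 1 bp. Expected values came from 200 random placements of each list with lengths kept, either on the own chromosome or within the own 1 Mb, over the 2906 bins of 1 Mb that held a gene or a peak; this stood in for the exclusion of assembly gaps. Observed summits were compared with the centres of placed peaks. One-sided permutation p-values count placements at least as extreme, and 0.005 is the smallest that can result.

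Gene positions were those of a RefSeq gene table of GRCh38.p14, the same build as the peaks. It gives no strand and no exons, and no genome sequence was used here. The planned promoter window around the transcription start was therefore replaced by windows of 1000 bp on either side of both gene ends, the planned exon class was left out, and GC content, CpG content and backgrounds matched on GC were not analysed here. Rows of the table on scaffolds or alternate loci listed under a chromosome (679 genes) were dropped, which left 58415 genes, 19817 of them protein-coding and 17904 long non-coding RNA genes.

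The 29 gene lists, by symbol or by name pattern, were fixed before the data were examined, and all 1900 list entries matched the gene table. They covered repair pathways, housekeeping complexes, stress, p53 and Wnt targets, markers of colorectal epithelium and of other tissues, and multigene families. A list was tested with a two-sided Fisher's exact test on genes with a gene-end peak in at least 2 of 3 replicates against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists at 0.05. The rule for named genes, fixed at the same time, took the 20 protein-coding genes and the 10 regions with peaks in all 3 replicates and the highest mean rank of fold within a replicate. It added up to 4 such members of each list that passed and up to 2 of each list that did not, and a fixed set of genes whatever their values, of which NEIL1, NEIL2, OGG1, NTHL1, EP300, POLR2A, MYC, CDKN1A and KEAP1 are given. A few genes that the rule takes are not reported here.

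Correlations across chromosomes used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. Alternatives were stricter peaks, equal numbers of peaks, the 5000 strongest peaks, leaving out each replicate, reciprocal overlap, placement within the own 1 Mb, other windows, peak centres in place of whole peaks, other numbers of replicates, and fewer chromosomes. Lists matched on neighbours or on regional peak density together with gene length (10000 random lists), each replicate alone, differences between replicates against those of other genes (Fisher's exact test), the strength of shared regions peak by peak, chromosome X left out and genes oriented by a divergent transcript were added after seeing the data.

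The placement and list tests were tested on simulated data. With 5000 shared regions planted in each list, 5112 were found against 144.5 expected by chance, and a planted rise of 4.01 percentage points at the ends of the 19817 protein-coding genes was measured as 3.78. With genes drawn at random, 3.50% of 200 rounds called any of the 29 lists, and a list of 40 genes at 3 times the background was called in 91.0% of rounds. Genes were drawn independently of each other, so these rates do not cover lists whose neighbouring genes share peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.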

Results

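Acetylated NEIL1 (AcNEIL1) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HCT116, a human colorectal carcinoma cell line. NEIL1 is a DNA glycosylase that removes oxidised bases at the start of base excision repair, and the antibody was raised against its acetylated form. The series held 6 libraries: 3 AcNEIL1 ChIP libraries, replicates 1 to 3, and 3 input libraries of sheared chromatin without immunoprecipitation. Peak lists of the 3 ChIP libraries were analysed, each called by the authors against the input library of the same number. After the caller's duplicate filter the ChIP libraries held 31921768, 28814429 and 35222701 tags in replicates 1, 2 and 3, and the inputs held 32877739, 37772127 and 33606858. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. There was no second condition, and every comparison is between replicates or between parts of the genome.

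AcNEIL1 peaks were numerous, narrow and weak. The lists held 39898, 60233 and 49731 peaks in replicates 1, 2 and 3, a mean of 49954 ± 10169 (SD, n = 3). Median width was 401, 478 and 384 bp, and the peaks covered 21.5, 45.1 and 26.5 Mb of chromosomes 1 to 22 and X. The authors' fold enrichment at the summit had a median of 3.42, 3.40 and 3.61. A fold below 5 was found for 95.5% ± 1.01 (SD, n = 3) of the peaks. At the stricter −log10 q of 5 or more, 11374, 24593 and 14275 peaks were left. Replicate 2 had the fewest ChIP tags and the most peaks, and it was also the replicate with the deepest input.

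The first comparison asked whether the 3 libraries marked the same places. Merging the lists gave 85534 regions, of which 11329 (13.2%) had a peak in all 3 replicates, 15794 in 2 and 58411 (68.3%) in 1. The strongest shared region lay on chromosome 22 at 19723580 to 19730053 (hg38), from the end of SEPTIN5 across GP1BB, the gene of a platelet membrane glycoprotein, with fold 10.3 ± 2.66 (SD, n = 3). Next by mean rank of fold came a region inside COL7A1, the gene of an anchoring-fibril collagen, on chromosome 3 at 48565740 to 48578030, with fold 7.56 ± 0.722 (SD, n = 3). An intergenic region on chromosome 19 at 2054968 to 2060069 had fold 7.98 ± 1.21 (SD, n = 3), and the nearest protein-coding gene was MKNK2, 3724 bp away. The region on chromosome 17 at 81937927 to 81942981 touched the ends of PYCR1, a proline biosynthesis gene, and MYADML2, with fold 7.66 ± 1.03 (SD, n = 3).

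The other regions among the 10 highest in mean rank of fold had mean folds between 6.99 and 7.90. They lay inside AATK, a kinase gene, on chromosome 17 (81120081 to 81137045), where the ends of MIR657, MIR3065, MIR338 and MIR1250 also fell. Others were inside MUC4, a membrane mucin gene, on chromosome 3 (195778700 to 195789188) and inside NR5A1, a gene of steroid-producing tissue, on chromosome 9 (124492944 to 124504798). The region on chromosome 1 (8206780 to 8211953) touched the end of LINC01714, and that on chromosome 21 (43397508 to 43403123) the end of LINC03039, both long non-coding RNA genes. The last, on chromosome 22 (37782992 to 37784730), lay 6436 bp from TRIOBP. The annotation used gave no exons, so intron, exon and UTR positions were not analysed here.

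**Figure D1:**
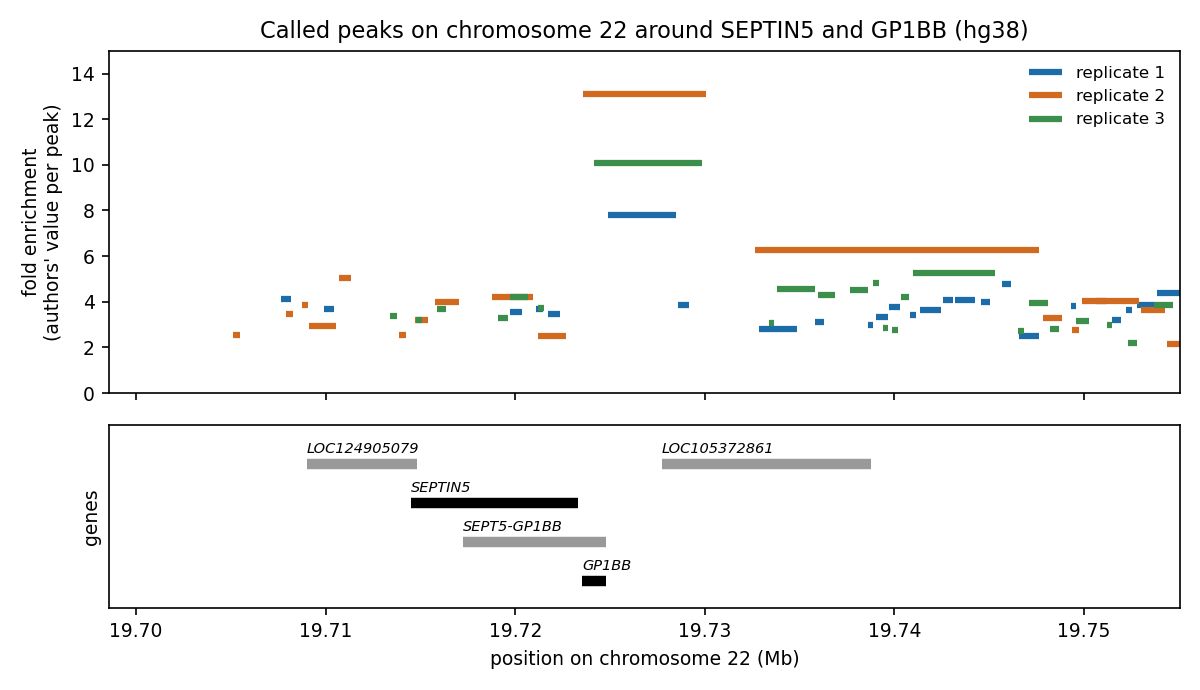
Called AcNEIL1 peaks around SEPTIN5 and GP1BB on chromosome 22 (hg38). The upper panel draws each peak of replicates 1, 2 and 3 as a bar from its start to its end (x axis, Mb) at the authors' fold enrichment (y axis), and the lower panel draws protein-coding genes in black and long non-coding RNA genes in grey. The peaks over GP1BB reach fold 7.80, 13.1 and 10.1 in replicates 1, 2 and 3.

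The number of regions shared by all 3 replicates exceeded random placement. Placing each list at random on its own chromosomes gave 145.7 shared regions on average (range 117 to 184), so the observed count was 77.7 times the expected one (permutation p = 0.005, one-sided, the smallest that 200 placements can give). Placing each peak within its own 1 Mb, which keeps the regional density, gave 1304 (range 1235 to 1392), and the ratio was then 8.69 (permutation p = 0.005, one-sided, again the smallest possible). Of the peaks of replicate 1, 60.6% overlapped a peak of replicate 2, and of replicate 3, 60.1% did. In the other direction 32.2% of the longer replicate 2 list overlapped replicate 1 and 39.7% overlapped replicate 3. The expected overlap of these pairs was between 2.65% and 4.00%. The count of shared regions depended on the peaks admitted: it was 3436 at −log10 q of 5 or more and 613 among the 5000 strongest peaks of each list. When a 50% reciprocal overlap was asked, peaks of replicate 1 were counted in place of merged regions. Of these, 1808 had such a partner in both other lists. Without replicate 1, 20463 regions were shared by replicates 2 and 3.

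Peak strength was set against the number of replicates that shared a region. The strongest peak of a region had a median fold of 3.67, 3.98 and 3.98 in replicates 1, 2 and 3 for shared regions and 3.42, 3.29 and 3.52 for regions seen in that replicate alone. Shared regions were also wider, with a median of 1709 bp against 329, 395 and 313 bp, and could hold several peaks of a replicate. Merging overlapping peaks of 3 lists widens a region by itself. Single peaks had a median width of 498, 858 and 514 bp in shared regions of replicates 1, 2 and 3, against the same 329, 395 and 313 bp. Taken peak by peak, a comparison added after seeing the data, the median fold was 3.42, 3.76 and 3.67 in shared regions and 3.42, 3.29 and 3.52 in the others, so replicate 1 then showed almost no difference in fold. The median −log10 p per peak was 7.47, 9.14 and 7.57 in shared regions and 6.09, 6.26 and 6.07 in the others. With 3 libraries these differences were not tested. The authors' fold was only loosely ordered alike: across the 11329 shared regions, which are not independent replicates, Pearson's r of log2 fold was 0.30, 0.35 and 0.35 for the pairs 1 and 2, 1 and 3, and 2 and 3, with Spearman's rho of 0.271, 0.322 and 0.328.

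The second comparison asked whether AcNEIL1 peaks lay at promoters, since the study's title speaks of repair complexes at open chromatin. The gene table gave no strand, so both ends of each protein-coding gene were used. Of the peaks, 9.96%, 10.4% and 9.66% in replicates 1, 2 and 3 overlapped a window of 1 kb either side of a gene end, a mean of 10.0% ± 0.368 (SD, n = 3). Random placement on the own chromosome gave 4.05%, and the ratio was 2.47 ± 0.0496 (SD, n = 3), with permutation p = 0.005 (one-sided, the smallest possible) in each replicate. Within the own 1 Mb the expected share was 7.22% and the ratio 1.39 ± 0.0242 (SD, n = 3, with permutation p = 0.005, one-sided, in each replicate). Peaks were placed singly, so clusters of peaks were not kept and these p-values may be too small. Counted by gene, 16.6% ± 3.18 of protein-coding genes had a gene-end peak against 16.4% expected within the own 1 Mb. That ratio was 1.01 ± 0.0392 (SD, n = 3), above 1 in replicates 1 and 2 and below 1 in replicate 3.

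Of the peak summits, 12.4% ± 0.258 fell within 1 kb of an end of a protein-coding or long non-coding RNA gene, 59.8% ± 0.110 in the rest of a gene body and 27.8% ± 0.152 between genes (SD, n = 3 for each). Random placement on the own chromosome gave 5.49%, 54.2% and 40.3%. Within the own 1 Mb it gave 8.85%, 59.9% and 31.3%, so gene bodies then held about their expected share.

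Of 19817 protein-coding genes, 2773, 3990 and 3093 had a gene-end peak in replicates 1, 2 and 3. In at least 2 replicates 3021 genes (15.2%) had one, and 1790 (9.03%) had one in all 3. The 20 genes with a peak in all 3 and the highest mean rank of gene-end peak fold had mean folds from 6.10 to 10.3. Of these, 6 lay on chromosome 17, among them the overlapping genes DNAAF19, FAM187A and GFAP. That chromosome held 9.9%, 9.2% and 10.1% of the peaks analysed in replicates 1, 2 and 3. Whether the strongest genes favour it beyond its share of peaks was not tested. Among the 20 genes, GP1BB led with fold 10.3 ± 2.66, followed by MYADML2 (7.66 ± 1.03) and PHYHIP (7.35 ± 1.76; SD, n = 3 for each). HRC, a calcium-binding protein of the muscle sarcoplasmic reticulum, and its neighbour TRPM4, a cation channel, shared a peak of fold 7.01 ± 1.19 (SD, n = 3). DNAAF19 and FAM187A shared one of 7.08 ± 1.17, and GFAP, the intermediate filament of astrocytes, which overlaps both genes, had 6.69 ± 1.27 (SD, n = 3). APOBR, a lipoprotein receptor, and IL27, a cytokine, shared one of 7.14 ± 1.61 (SD, n = 3).

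The other genes of this set had mean folds from 6.10 to 6.73. NES, the neural progenitor filament nestin, had fold 6.73 ± 1.70, and SLC2A4, the insulin-responsive glucose transporter of muscle and fat, had 6.64 ± 1.12 (SD, n = 3). ROBO4, an endothelial receptor, had 6.56 ± 1.49, and SNCG, a synuclein, had 6.39 ± 0.387 (SD, n = 3). GNLY, a granule protein of cytotoxic lymphocytes, had 6.26 ± 0.666, and PDCD1, an inhibitory receptor of T cells, had 6.21 ± 0.198 (SD, n = 3). The monocarboxylate transporter gene SLC16A3 had 6.66 ± 1.33, the zinc transporter gene SLC30A2 6.20 ± 0.453 and LCNL1 6.10 ± 0.344 (SD, n = 3). The set was completed by LOC124902171, with 6.30 ± 0.608 (SD, n = 3).

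A set of genes fixed before the data were examined is given whatever the values. NEIL1, NEIL2 and OGG1, which encode glycosylases for oxidised bases, had no gene-end peak in any of the 3 replicates, and the nearest peak edge lay 1.82, 7.40 and 14.2 kb from a gene end. EP300, which encodes an acetyltransferase, POLR2A, the large subunit of RNA polymerase II, MYC and KEAP1 also had none; of all protein-coding genes 74.5% had none in any replicate. NTHL1, a glycosylase gene, had a peak of fold 3.14 in replicate 2 only, and CDKN1A, a cell cycle inhibitor gene, had one of fold 3.46 in replicate 3 only.

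The third comparison asked which gene groups carried AcNEIL1 peaks at their ends. Of 29 lists fixed before the data were examined, 5 held more genes with a peak in at least 2 replicates than the other protein-coding genes did, 10 held fewer and 14 were not called. All p-values of this comparison come from two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 29 lists, except those against genes matched on regional peak density and gene length, a two-sided permutation test added after seeing the data and adjusted in the same way. Both tests take genes as independent, although neighbouring genes can share a peak. Lists of clustered genes, such as HOX genes and protocadherins, may thus hold fewer independent members than counted, and their p-values may be too small.

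Striated muscle markers had the highest share: 19 of 32 genes (59.4%) had a gene-end peak against 15.2% of other genes, a ratio of 3.91 (adjusted p = 1.28e-07, Fisher's exact test). The share was 57.3% ± 3.61 over the replicates (SD, n = 3), and 15 of the genes had a peak in all 3. Troponin genes led, with TNNI2 at fold 5.59 ± 1.68, TNNT3 at 5.57 ± 1.96, TNNI1 at 4.78 ± 0.452 and TNNC2 at 4.28 ± 0.274 (SD, n = 3). HOX genes, which encode transcription factors of body patterning, followed with 21 of 39 (53.8%), a ratio of 3.55 (adjusted p = 1.81e-07, Fisher's exact test) and 56.4% ± 4.44 over the replicates (SD, n = 3). Among them were HOXC8 (fold 4.97 ± 1.16), HOXD10 (4.72 ± 1.14), HOXD12 (4.66 ± 0.345) and HOXD9 (4.29 ± 0.617; SD, n = 3). Both calls were lost when the 5000 strongest peaks of each list were used alone (ratio 3.76, adjusted p = 0.262 for muscle and 2.05, adjusted p = 1.0 for HOX genes, Fisher's exact test). The muscle ratio was 1.94 with windows of 5000 bp (adjusted p = 0.00156) and 2.58 with a peak in any replicate (adjusted p = 1.44e-05, Fisher's exact test for both), and the HOX ratio was 2.36 against genes matched on regional peak density and length (adjusted p = 0.000967, permutation test).

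Blood cell markers had a gene-end peak in 13 of 34 genes (38.2%, ratio 2.52, adjusted p = 0.00383, Fisher's exact test) and in 40.2% ± 4.49 over the replicates (SD, n = 3). They included GNLY (fold 6.26 ± 0.666), the B cell gene CD79A (5.80 ± 0.540) and PRF1, the gene of perforin (5.20 ± 0.672; SD, n = 3). With windows of 5000 bp the ratio was 1.46 and the call was lost (adjusted p = 0.125, Fisher's exact test), as it was against genes matched on regional peak density and length (ratio 1.73, adjusted p = 0.0658, permutation test). Fibroblast and endothelial markers had one in 8 of 23 (34.8%, ratio 2.29, adjusted p = 0.0321, Fisher's exact test). The members with the strongest peaks in all 3 replicates, ROBO4 (6.56 ± 1.49), ESAM (4.39 ± 0.494), CLDN5 (4.06 ± 0.784) and CDH5 (3.71 ± 0.854; SD, n = 3), are endothelial. This call was lost under 11 of 15 alternatives, among them without replicate 1 (ratio 1.74, adjusted p = 0.301, Fisher's exact test) and without replicate 2 (2.64, adjusted p = 0.0626, Fisher's exact test).

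Immediate early and stress genes had a gene-end peak in 12 of 30 (40%, ratio 2.63, adjusted p = 0.00383, Fisher's exact test), but not alike in the 3 libraries: 11 genes in replicate 1, 4 in replicate 2 and 12 in replicate 3. In all 3 replicates 2 members had a peak, the heat shock gene HSPA1A (fold 4.23 ± 1.01) and FOSL1, a Fos family gene (2.81 ± 0.174; SD, n = 3). Without replicate 1 the ratio was 0.801 and without replicate 3 it was 0.915 (adjusted p = 1.0 in both, Fisher's exact test). Both settings required a peak in replicate 2. Against genes matched on regional peak density and length the ratio was 1.73 and this call was lost too (adjusted p = 0.0725, permutation test).

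Proteasome, oxidative phosphorylation, RNA polymerase II and histone genes had few gene-end peaks, while ribosomal protein and glycolysis genes, also used in all cells, were not called. None of 33 proteasome genes had one in at least 2 replicates (adjusted p = 0.0175, Fisher's exact test), and a count of 0 allows a share of up to 9.09%. Of 56 oxidative phosphorylation genes 2 had one, among them NDUFA8 (fold 4.03 ± 1.41; SD, n = 3), a ratio of 0.234 (adjusted p = 0.0215, Fisher's exact test). Of 41 genes of RNA polymerase II and general transcription 1 had one, POLR2F, at fold 5.38 ± 1.66 (SD, n = 3), a ratio of 0.160 (adjusted p = 0.0321, Fisher's exact test). These 3 calls did not hold when any 1 replicate was left out and a peak was required in both others: without replicates 1, 2 and 3 adjusted p was 0.0652, 0.139 and 0.100 for the proteasome, 0.0783, 0.253 and 0.154 for oxidative phosphorylation and 0.0942, 0.253 and 0.191 for the RNA polymerase II list (Fisher's exact test). The ratios stayed low, at 0 in each case for the proteasome, 0.286, 0.360 and 0.326 for oxidative phosphorylation and 0.195, 0.246 and 0.223 for the RNA polymerase II list. With windows of 5000 bp the ratios of the 3 lists were 0.375, 0.663 and 1.13. Replication-dependent histone genes had a peak in 2 of 69 (2.90%, ratio 0.190, adjusted p = 0.00738, Fisher's exact test) and in none without replicate 1 (adjusted p = 0.000797, Fisher's exact test). The histone call was lost with the 5000 strongest peaks (ratio 0, adjusted p = 1.0) and in replicate 1 alone (ratio 0.413, adjusted p = 0.104), and with windows of 5000 bp the ratio was 0.583 (adjusted p = 0.0434, Fisher's exact test for each). A ratio of 0 is the lowest possible, so the loss with the 5000 strongest peaks does not show a smaller depletion.

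Several large gene families had few gene-end peaks too. Of 387 olfactory receptor genes 1 had a gene-end peak in at least 2 replicates (0.258%, adjusted p = 2.52e-25, Fisher's exact test; 0 without replicate 1 or without replicate 2), and of 509 zinc finger ZNF genes 23 did (4.52%, adjusted p = 1.45e-13, Fisher's exact test). ZNF574 (fold 4.88 ± 0.680), ZNF467 (4.64 ± 0.605), ZNF683 (4.33 ± 0.315) and ZNF837 (3.95 ± 0.199; SD, n = 3) had the strongest of these. None of 50 clustered protocadherin genes (adjusted p = 0.00291), 39 beta-defensin genes (adjusted p = 0.00811) or 38 MAGE and GAGE cancer-testis genes (adjusted p = 0.00811, Fisher's exact test for each) had one. Counts of 0 allow shares of up to 6%, 7.69% and 7.89%. Without replicate 2 the beta-defensin and the MAGE and GAGE calls were lost with a count of 0 still (adjusted p = 0.0710 for both, Fisher's exact test), and with windows of 5000 bp the protocadherin ratio was 1.24. For the MAGE and GAGE genes, genes matched on regional peak density and length had a share of only 5%, and the call was lost against them (adjusted p = 0.327, permutation test). Keratin-associated protein genes had a peak in 6 of 94 (6.38%, ratio 0.418, adjusted p = 0.0307, Fisher's exact test), KRTAP5-6 among them at fold 4.16 ± 1.29 (SD, n = 3), with 2, 13 and 7 genes in replicates 1, 2 and 3. The ratio was 0.425 without replicate 1 (adjusted p = 0.0783), 0.107 without replicate 2 (adjusted p = 0.00573) and 0.194 without replicate 3 (adjusted p = 0.0121, Fisher's exact test for each), and the call was lost under 6 of 15 alternatives.

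DNA repair lists were not called on peaks in at least 2 replicates. Base excision repair, the pathway of NEIL1, had a gene-end peak in 1 of 29 genes (3.45%, ratio 0.226, adjusted p = 0.166, Fisher's exact test), and with windows of 5000 bp the ratio was 1.07. Nucleotide excision repair had 1 of 27, RAD23B at fold 4.00 ± 0.123 (SD, n = 3; adjusted p = 0.166, Fisher's exact test). Mismatch repair had 1 of 17 (adjusted p = 0.564) and double-strand break repair 1 of 34 (ratio 0.193, adjusted p = 0.0839, Fisher's exact test for both). The double-strand break list was called below other genes under 4 of 15 alternatives: with windows of 5000 bp (ratio 0.273, adjusted p = 0.00770), with a peak in any replicate (0.115, adjusted p = 0.00363), in replicate 2 alone (0.146, adjusted p = 0.0193) and in replicate 3 alone (0, adjusted p = 0.0184, Fisher's exact test for each).

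Cytosolic ribosomal protein genes stood near the background in at least 2 replicates, with 11 of 77 (14.3%, ratio 0.937, adjusted p = 1.0, Fisher's exact test), yet the libraries differed: 24 had a peak in replicate 1, 4 in replicate 2 and 13 in replicate 3. Taken alone, replicate 1 gave a ratio of 2.24 (adjusted p = 0.000548) and replicate 2 a ratio of 0.257 (adjusted p = 0.00130, Fisher's exact test for both). RPS19 (fold 3.34 ± 0.977; SD, n = 3) was among the members with peaks in all 3 replicates.

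The remaining lists did not pass the adjusted threshold. Hepatocyte markers had 9 of 29 (31.0%, adjusted p = 0.0594, Fisher's exact test), with APOC3 at fold 4.12 ± 0.536 and SERPINA1 at 4.24 ± 0.957 (SD, n = 3). Neuronal markers, a list that includes the astrocyte gene GFAP, had 8 of 32 (25.0%, adjusted p = 0.189), with GFAP at 6.69 ± 1.27 and SLC32A1 at 4.93 ± 0.286, and Wnt targets had 5 of 20 (25.0%, adjusted p = 0.283, Fisher's exact test for both), with TCF7 at 4.59 ± 1.48 and ASCL2 at 3.86 ± 0.605 (SD, n = 3). Against genes matched on regional peak density and length, neuronal markers were called above (ratio 2.30, adjusted p = 0.0388, permutation test). Colorectal epithelial markers, the cell type of origin, had 6 of 25 (24.0%, adjusted p = 0.323, Fisher's exact test), with LGALS4 at 5.38 ± 0.540 and CDX1 at 3.61 ± 0.952 (SD, n = 3). For p53 targets the count was 4 of 23 (adjusted p = 0.827, Fisher's exact test), with PLK3 at 4.58 ± 0.769 and BAX at 4.10 ± 1.07 (SD, n = 3). Antioxidant and NRF2 targets had 4 of 31 (adjusted p = 1.0), cell cycle genes 3 of 40 (adjusted p = 0.323), glycolysis genes 1 of 18 (adjusted p = 0.564) and bitter taste receptors 0 of 24 (adjusted p = 0.0691, Fisher's exact test for each), where a count of 0 allows up to 12.5%. FTH1 (4.00 ± 0.665) and CCND1 (2.98 ± 0.558; SD, n = 3) were members with peaks in all 3 replicates.

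**Figure D2:**
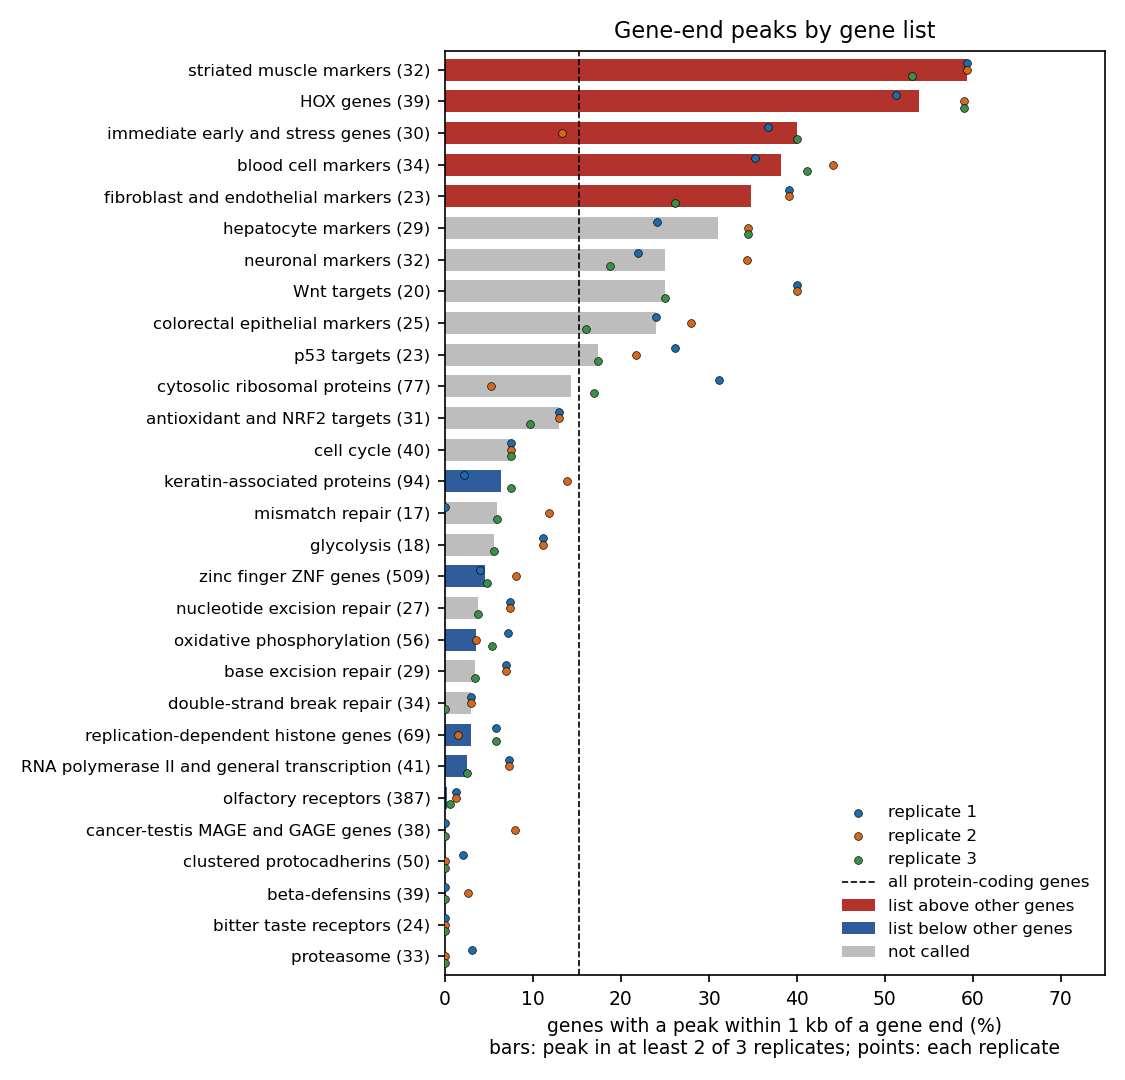
Share of each gene list with an AcNEIL1 peak within 1 kb of a gene end (x axis, %), with the number of genes in parentheses. Bars give genes with a peak in at least 2 of 3 replicates, points give each replicate and the dashed line marks 15.2%, the share of all protein-coding genes. Striated muscle markers reach 59.4% and HOX genes 53.8%, while the points of ribosomal protein genes lie apart.

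The fourth comparison set peak density against gene density by chromosome. Peaks were densest on chromosome 17 (59.5 ± 9.86 per Mb), chromosome 22 (58.6 ± 12.6), chromosome 19 (47.7 ± 10.4) and chromosome 16 (35.3 ± 5.92; SD, n = 3). The local background at peaks, averaged over replicates, was highest on chromosome 17 (6.35 tags). It was 5.80 on chromosome 16, 5.04 on chromosome 22 and 4.87 on chromosome 19. Chromosome 8 had 5.85 with only 12.6 peaks per Mb. How far tag coverage sets these densities was not tested. The gene-poor chromosomes 13 (5.68 ± 1.30) and 18 (6.36 ± 1.36) had the lowest densities among the autosomes, and chromosome X had 1.28 ± 0.734 (SD, n = 3). Across the 23 chromosomes, which are not replicates, mean density correlated with protein-coding genes per Mb with Pearson's r of 0.80 (permutation p = 6e-05, two-sided) and Spearman's rho of 0.90 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). Without chromosomes 17 and 19, the farthest from the median in gene density, r was 0.86. Chromosome X, with 5.54 genes per Mb, stood below all 8 autosomes that have no more genes per Mb than it has.

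**Figure D3:**
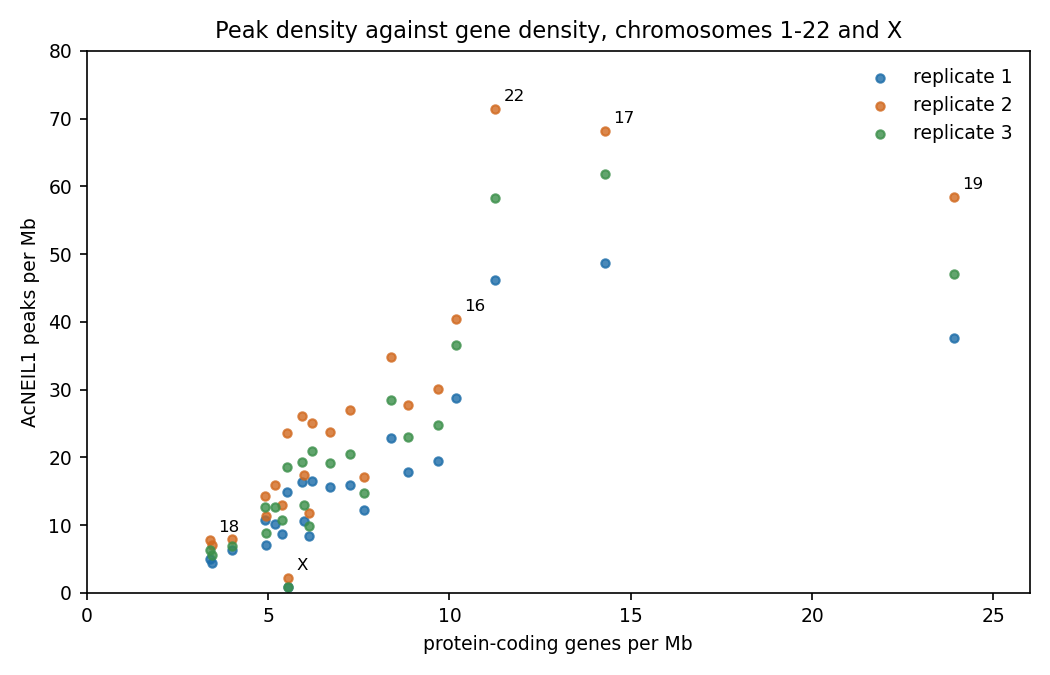
AcNEIL1 peaks per Mb (y axis) against protein-coding genes per Mb (x axis) for chromosomes 1 to 22 and X, 1 point per chromosome and replicate. Chromosomes 17 and 22 lie highest, with means of 59.5 and 58.6 peaks per Mb, and chromosome X lies lowest, with 1.28.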

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

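The tests of each list against matched genes, of ribosomal protein and immediate early genes and of chromosome X were chosen after the results were seen; the background test of tissue markers was set before it was run, but on lists picked because they had passed.

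Peaks were also called on sequences outside chromosomes 1 to 22 and X, which no comparison used. Unlocalised and unplaced scaffolds held 105, 143 and 116 peaks in replicates 1, 2 and 3, and chromosome Y held 4, 15 and 6. One scaffold assigned to chromosome 11 (11_KI270721v1_random) held 34, 41 and 31 peaks between positions 2782 and 96092, or 378.7 ± 55.0 per Mb (SD, n = 3), against 24.7 ± 5.34 per Mb on chromosome 11 itself. The scaffold Un_GL000220v1 held 9, 9 and 9 peaks and 22_KI270733v1_random held 9, 9 and 11, with pileups of up to 946 and 881 tags in replicate 1. The highest folds there in replicate 1 were only 3.69 and 4.08, so the local background at these pileups was high too. The ribosomal RNA genes RNA45SN1, RNA45SN2 and RNA45SN3 on chromosome 21 overlapped 0 peaks in each replicate. Other copies of these genes were not analysed here, so this does not show that ribosomal RNA genes lack signal.

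Gene ends of muscle, blood, fibroblast and endothelial markers and HOX genes carried peaks more often than other genes, and those of proteasome, oxidative phosphorylation and RNA polymerase II genes less often, though the fibroblast and endothelial call and the last 3 were lost under 8 to 12 of 15 alternatives. Each of the 29 lists was set against genes matched on gene length with regional peak density or with neighbours, which argues against these as the whole cause for striated muscle markers (ratios 2.82 and 3.19, adjusted p = 0.000967 and 0.000829), HOX genes (2.36 and 2.28, the same p-values) and fibroblast and endothelial markers (3.29 and 2.91, adjusted p = 0.00129 and 0.0139, permutation tests, two-sided, adjusted over the lists). Matched genes were drawn 1 by 1, so peaks shared by neighbouring list members were not kept. The p-values of clustered HOX genes may therefore be too small. For blood cell markers the ratio fell from 2.52 to 1.73 with regional density matched, where the matched share rose to 22.2%, and the call ended (adjusted p = 0.0658), so density stays open for them, while neighbours left 1.88 (adjusted p = 0.0381, permutation tests); of the other tissue lists, with regional density matched, neuronal markers stood at 2.30 (adjusted p = 0.0388), hepatocyte markers at 2.11 (adjusted p = 0.0518) and colorectal markers at 1.016 (adjusted p = 1.0, permutation tests). The same 2 matchings left the proteasome at 0 (adjusted p = 0.00174 and 0.00677), oxidative phosphorylation at 0.198 and 0.203 (adjusted p = 0.00422 and 0.00633) and the RNA polymerase II list at 0.111 and 0.127 (adjusted p = 0.00129 and 0.00580), while ribosomal protein genes stood at 0.591 (adjusted p = 0.0658) and glycolysis genes at 0.265 (adjusted p = 0.203, permutation tests) with regional density matched. The local background at the first group's gene-end peaks was at least 1.00 times that at other gene-end peaks in each replicate, but this compares called peaks only, so a low input signal at these genes stays open, as do GC and CpG content, not analysed here, and no biological explanation was tested, since the design has 1 group of ChIP libraries.

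Ribosomal protein genes (24 against 4 of 77) and immediate early genes (11 against 4 of 30) had fewer gene-end peaks in replicate 2 than in replicate 1. Fewer peaks in replicate 2 was not an open explanation, since its list was already known to be the longest. The share of all protein-coding genes with a gene-end peak was 1.44 times as high in replicate 2 as in replicate 1. Sampling of genes is argued against: of ribosomal protein genes 21 had a peak in replicate 1 and not 2 and 1 the reverse, against 587 and 1824 other genes (adjusted p = 2.55e-10), and of immediate early genes 8 and 1, against 600 and 1824 (adjusted p = 0.00225, Fisher's exact tests, two-sided, adjusted over 87). Of these 87 tests over 29 lists and 3 pairs of replicates 5 had an adjusted p under 0.05, all for these lists, while McNemar's exact test against equality gave adjusted p = 0.000954 for the ribosomal protein genes and 0.425 for the immediate early genes between replicates 1 and 2. A difference in the input, the chromatin preparation or the state of the cells stays open, with 1 library behind each replicate.

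Chromosome X held 1.28 ± 0.734 peaks per Mb (SD, n = 3), and low gene density is argued against, since the lowest of the 8 autosomes with no more genes per Mb than X had 5.68 and X lay below each of the 8 in every replicate. Lower tag coverage of X may contribute: the median background at X peaks was 0.640 ± 0.0521 times that at autosomal peaks (SD, n = 3), and 63.5% ± 5.56 of X peaks lay within 2% of the background floor against 8.26% ± 4.26 of autosomal ones (SD, n = 3). The median at X peaks, 3.17, 3.14 and 3.10 tags in replicates 1, 2 and 3, lay at the floor. The ratio therefore cannot show how much lower the coverage of X was. Pileup and background of autosomal peaks were then halved on paper, with the background kept from falling below its floor. Of these peaks 47.5% ± 7.35 still passed the caller's lowest p (SD, n = 3). At most peaks the floor was reached, so pileup was lowered by a larger factor than background. Chromosomes 10, 2 and 3, close to X in gene density, then kept 9.17 ± 3.28, 5.39 ± 2.01 and 4.47 ± 1.71 peaks per Mb (SD, n = 3), and chromosome 18, then the lowest autosome, kept 2.01 ± 0.739 (SD, n = 3): 1.61, 2.86 and 1.56 in replicates 1, 2 and 3 against 0.876, 2.12 and 0.830 on X. After halving, each of the 8 autosomes still lay above X in all 3 replicates. Whether X holds fewer AcNEIL1 sites stays open, as the halving is assumed and the coverage of X outside peaks was not analysed here.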

How the results depend on the processing

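Lists matched on neighbours or regional density, each replicate alone, strength peak by peak and chromosome X left out were chosen after seeing the data. The excess of shared regions over random placement (ratios 8.69 to 1022), the enrichment of peaks at gene ends (1.39 to 2.84) and the correlation of peak and gene density (r 0.79 to 0.92) kept their direction and their side of the threshold under each alternative run on them. Counted by gene in place of by peak, the mean ratio for protein-coding gene ends within the own 1 Mb was 1.01. Counts moved more, and the cause was not tested beyond the number of peaks or replicates each setting admits. Regions shared by all replicates numbered 3436 at −log10 q of 5 or more, 613 among the 5000 strongest peaks and 15970 to 20463 with 1 replicate left out. With 50% reciprocal overlap, 1808 peaks of replicate 1, counted in place of merged regions, had a partner in both other lists. The 5 lists above and 10 below other genes became 3 and 4 at −log10 q of 5 or more, 1 and 2 with the 5000 strongest peaks, 3 and 5 with 500 bp windows, 3 and 4 with a peak in all 3 replicates, 7 and 6 for replicate 1 alone, 3 and 10 for replicate 2 alone, and 3 to 4 above and 5 to 7 below with 1 replicate left out. With 1 replicate left out, a peak was required in both remaining replicates. Among the 5000 strongest peaks, the proteasome, oxidative phosphorylation, histone, keratin-associated protein, beta-defensin, protocadherin and MAGE and GAGE ratios were 0. Those calls were lost at the lowest possible ratio, so their loss there does not show a smaller depletion. Of the 15 called lists, 2 (olfactory receptors and ZNF genes) had the same call under all 15 alternatives, and 79 calls of the other lists changed (1 each for striated muscle and HOX genes, 2 each for blood cell markers and histone genes, 4 for protocadherins, 5 for beta-defensins, 6 for keratin-associated proteins, 7 for MAGE and GAGE genes, 8 for the proteasome, 9 for immediate early genes, 11 each for oxidative phosphorylation and fibroblast and endothelial markers and 12 for the RNA polymerase II list); 8 of the 14 lists not called were called by some alternative: double-strand break repair under 4 and bitter taste receptors under 5, both below other genes, ribosomal protein genes above in replicate 1 alone and below in replicate 2 alone, Wnt targets above with a peak in any replicate and in replicate 1 alone, colorectal markers above with 5000 bp windows, hepatocyte markers above in replicate 3 alone, neuronal markers above with regional density matched and cell cycle genes below with 500 bp windows. Striated muscle and HOX calls were lost with the 5000 strongest peaks alone among the 15 (adjusted p = 0.262 and 1.0; over their alternatives 1.54e-08 to 0.262 and 1.62e-11 to 1.0, Fisher's exact or permutation test), the fibroblast and endothelial call under 11, and blood cell markers with 5000 bp windows and with matching on regional density. That matching also ended the calls of immediate early genes (ratio 1.73, adjusted p = 0.0725; over their alternatives 0.000162 to 1.0) and of MAGE and GAGE genes (adjusted p = 0.327; over their alternatives 7.11e-05 to 1.0, Fisher's exact or permutation tests). The median fold of regions shared by all replicates over that of regions in 1 was 1.14 with the strongest peak of each region, 1.06 peak by peak and 1.07 in regions with 1 peak of the replicate (means of 3 replicates). Among the called lists, the direction changed for immediate early and stress genes without replicate 1 (ratio 0.801) and without replicate 3 (0.915; without replicate 2 it was 3.38), with a peak in all 3 replicates (0.738) and in replicate 2 alone (0.662), and with 5000 bp windows for the RNA polymerase II list (1.13) and protocadherins (1.24). Ratios of some lists not called crossed 1 too, such as glycolysis genes with 5000 bp windows (1.55). Backgrounds matched on GC content were not run, as no genome was used. No paired analysis was possible because the input libraries, which share replicate numbers 1 to 3 with the ChIP libraries, entered through the peak calls only. The effect of depth was not tested, since the lists hold no reads.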

Other observations

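The orientation of genes and the gene classes were chosen for comparison after seeing the data. The gene table gave no strand, but 563 protein-coding genes could be oriented by an annotated divergent transcript (a long non-coding RNA named after the gene, starting next to its promoter) within 5000 bp. In replicate 1 the promoter end of these genes had a peak within 1 kb in 6.57% and the far end in 2.13% (adjusted p = 0.000511, exact McNemar test, two-sided, adjusted over the 3 replicates). In replicate 3 the shares were 4.97% and 2.49% (adjusted p = 0.0365), and in replicate 2 they were 6.57% and 5.51% (adjusted p = 0.480, exact McNemar tests, two-sided). The promoter was not where the share was highest: of the 1 kb bins up to 10 kb either side of the gene start, the bin from 5 to 4 kb upstream was highest in replicate 1 (5.15%) and that from 4 to 3 kb upstream in replicates 2 (8.17%) and 3 (7.11%), against 3.38%, 4.97% and 2.49% in the 1 kb before the start and 4.44%, 4.97% and 3.38% in the 1 kb after it. These bins were picked because they were highest, so the difference was not tested. A peak at either end was found in 8.17%, 10.5% and 6.75% of these genes in replicates 1, 2 and 3, against 13.99%, 20.1% and 15.6% of all protein-coding genes, a difference that was not tested.

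Gene classes differed from random placement, by an amount that depended on the placement. Of snoRNA genes 2.69% ± 0.0840 had a peak within 1 kb, 0.539 ± 0.114 times the share expected on the own chromosome and 0.356 ± 0.0591 times that within the own 1 Mb (SD, n = 3), and of pseudogenes 3.91% ± 1.07 did, 0.632 ± 0.0364 and 0.663 ± 0.0456 times (SD, n = 3). Both were lower in each replicate under both placements (permutation p between 0.005 and 0.0149, one-sided). For tRNA genes the ratios were 0.606 ± 0.0821 and 0.465 ± 0.0809 and for snRNA genes 0.870 ± 0.0597 and 0.584 ± 0.0761 (SD, n = 3); on the own chromosome snRNA genes did not differ in any replicate (permutation p from 0.373 to 0.488, one-sided) and tRNA genes did in replicate 3 only (permutation p = 0.0299, one-sided). For miRNA genes they were 2.17 ± 0.0952 and 1.18 ± 0.0466, for long non-coding RNA genes 1.35 ± 0.0808 and 1.10 ± 0.0370, for transcribed pseudogenes 1.29 ± 0.122 and 1.11 ± 0.102, and for protein-coding genes 1.595 ± 0.0870 and 1.01 ± 0.0392 (SD, n = 3). Within the own 1 Mb miRNA genes missed 0.05 in replicate 3 (permutation p = 0.0547, one-sided), and transcribed and protein-coding classes did not keep 1 direction over the replicates.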
